A study of Glycine max with 25 samples.

How the data were processed

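RNA of the first trifoliate leaves was measured on 25 Affymetrix soybean arrays, 5 biological replicates of each of the varieties 2601R, Bayfield, Mandarin, PS46R and S03W4. Plants grew under 16 h of light at 25 °C by day and 19 °C by night, from 10 seeds in 2 pots of 20 cm, and 5 µg of RNA was used. The deposited values are log2 expression values per probe set, which the authors made with RMA (background correction, quantile normalization and median polish); the settings and versions are not given in the sources used here. They were used as deposited. The images themselves were not used here.

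The 61170 probe sets were 37593 of soybean, 15820 of Phytophthora sojae, 7530 of Heterodera glycines and 227 controls. Of the soybean probe sets, 8677 had exactly 1 gene in the probe annotation, 370 several and 28546 none. A gene symbol other than a locus number was present for 1871 probe sets of 1121 genes. Gene order was used in 1 test, and genomic positions are not reported here.

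R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, were used. A limma model with variety as a factor was fitted to all soybean probe sets over the 25 arrays, with no block for replicate number. It gave a moderated F-test across varieties and the 10 pairwise contrasts, each adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. A probe set was specific to a variety when its 4 contrasts with the other varieties were all called with 1 sign. Set against each other were also 2601R with PS46R and the other 3 varieties, by limma on the 5 variety means, with the same contrast over arrays and the other ways to set 2 varieties against 3 beside it. Gene lists were tested with camera of limma at its preset correlation of 0.01 (30 lists in 10 contrasts, 300 tests adjusted together) and with an estimated correlation. The background was the 95th percentile of the pathogen probe sets.

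The tests, the rule for naming genes and most alternatives were chosen before the data were examined; the exceptions follow. The lists had been fixed as patterns for gene descriptions, but the tables used here give symbols only. They were rewritten as lists of gene symbols after the annotation had been seen and before any difference between varieties was computed, so 24 lists became 30, some families were added, and the lists for the shikimate pathway, transposable elements, allergens and histones had no member. The 30 lists are photosynthesis, chlorophyll and heme, carotenoids, vegetative storage proteins, lipoxygenases, jasmonate, protease inhibitors, seed storage and maturation, root nodule, flavonoids, phenylpropanoids, disease resistance, pathogenesis-related, heat shock, redox and glutathione S-transferases, cytochrome P450, UDP-glycosyltransferases, ribosomal proteins, clock with light and flowering, drought with cold and osmotic stress, cell division and wall growth, senescence, iron and phosphate, the WRKY, MYB, bZIP and NAC factors, aquaporins, sugar transport and glyoxalases. Seed and nodule lists are markers of other tissues.

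Named genes had exactly 1 gene and a symbol other than a locus number, which took the place of the gene description in the rule. They were, per variety, the 4 higher and 4 lower specific genes with the largest smallest difference; per pair, the 2 higher and 2 lower with the largest difference and no overlap between arrays; for 2 varieties against 3, the 10 higher and 10 lower with both means on 1 side; per list, up to 4 called members of the widest range; and the 5 probe sets of the widest range whatever their name. The rule also named every probe set of EPSPS, of which the tables used here name none. Values of LOC100500432 were chosen after they were seen.

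The 3′ index was planned as the mean over all control genes with 3′ and 5′ probe sets. After the values had been seen it was restricted to the 2 genes whose 5′ probe set was above background (a glutathione transferase and the second actin set). The permutation test across varieties, with 100000 permutations, gave p = 0.0687 with the restricted mean, 0.132 with the mean over all 6 control genes and 0.33 with the median.

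Alternatives were a filter on probe sets under the background, quantile normalization over soybean probe sets again, centring on pathogen probe sets, a trended and robust moderation, array weights, a replicate block (fixed and random), leaving out each array, leaving out probe sets that match several transcripts, adjustment over 10 contrasts together, a fit of the 2 compared varieties alone, other replicate units for 2 varieties against 3, and 1 value per gene for the lists. The index as a covariate, the analysis without the 5 arrays of index above 2.5 and the mean over all 6 control genes were chosen after seeing the data. Up to 100 regroupings of the arrays were drawn per count.

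The procedure was tested on simulated data with known changes. A planted difference of log2 0.5, 1 and 2 between Bayfield and Mandarin was called in 35.8%, 77.6% and 100% of the changed probe sets, with 8 unchanged among 164 called. The simulated noise was independent between probe sets, whereas in the real data 1 component held 43.1% of the variance within varieties. The false calls in the simulation therefore do not give the error rate in the real data. For 2 varieties against 3 on variety means, 86.6% of changes of log2 1 were called without differences between varieties and 0% with the real ones kept.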

Results

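The data were 25 Affymetrix soybean arrays, 5 for each of 5 soybean varieties named 2601R, Bayfield, Mandarin, PS46R and S03W4. Each array held RNA from expanded first trifoliate leaves of young plants, and the 5 arrays of a variety were biological replicates. The array carries 37593 soybean probe sets, 15820 probe sets of the oomycete Phytophthora sojae and 7530 of the nematode Heterodera glycines, 2 pathogens of soybean. The median soybean probe set lay between 4.62 and 4.87 on the log2 scale in every array. The 95th percentile of the pathogen probe sets, 2.59, served as the background, and 28137 soybean probe sets (74.8%) had a mean above it. Values are variety means of the log2 RMA value ± SD over the 5 arrays of the variety (n = 5), differences are in log2 ± SE, and "called" means an adjusted p under 0.05 in limma. The number of arrays limits the precision.

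The 3′ index of an array, the mean log2 excess of the 3′ over the 5′ probe set of 2 control genes, rises when the labelled RNA is shorter. It was 2.09 ± 0.96 in 2601R, 1.95 ± 0.66 in S03W4, 1.67 ± 0.24 in Mandarin, 1.25 ± 0.38 in PS46R and 1.16 ± 0.33 in Bayfield. A permutation test of the spread among variety means, one-sided for a larger spread, gave p = 0.0687 (adjusted p = 0.241 over 7 array measures). The index was above 2.5 in 5 arrays, replicates 2, 4 and 6 of 2601R (2.96, 2.61 and 2.74) and replicates 1 and 3 of S03W4 (2.63 and 2.68). Without these arrays, 2601R is represented by its replicates 3 and 5 alone and S03W4 by its replicates 2, 4 and 5. After each probe set was centred on its variety mean, the main component held 43.1% of the remaining variance. Across the 25 arrays it went with the index centred in the same way (Pearson's r = 0.971, Spearman's rho = 0.971, each with a permutation p of 1e-05, the smallest the permutations can give, and an adjusted p of 3e-05 over the 3 components tested). The other 2 components had a permutation p of 0.468 and 0.877 with the index. The correlation was 0.959 without the 2 arrays farthest from the median index. The share of soybean probe sets above background was 74.9% in Mandarin and between 74.1% and 74.6% in the other 4 varieties (permutation p = 0.00586, adjusted p = 0.041 over the 7 measures).

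**Figure D1:**
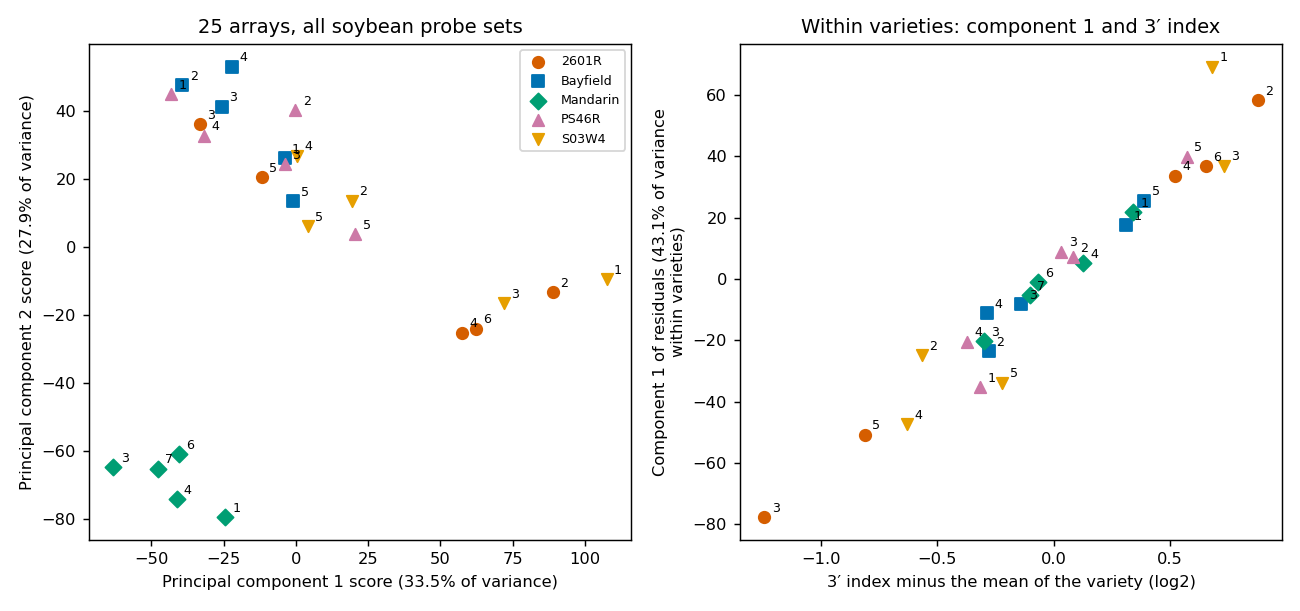
Left, the scores of the 25 arrays on principal components 1 and 2 of all soybean probe sets (33.5% and 27.9% of the variance), with a colour and symbol per variety and the replicate number beside each point, and right, the main component within varieties against the 3′ index minus its variety mean. The 5 Mandarin arrays stood apart on component 2, and the 5 arrays of index above 2.5 lay at the right of component 1.

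The comparison of all 5 varieties asks how much leaf gene expression varies between soybean lines. The probe sets with the widest ranges were high in some varieties and near or under the background of 2.59 in others. The probe set with the widest range, which has no gene in the tables used here, had 12.74 ± 0.18 in Mandarin and 12.56 ± 0.28 in S03W4, against 2.08 ± 0.26 in 2601R, 2.30 ± 0.22 in Bayfield and 2.34 ± 0.62 in PS46R. Another probe set without a gene had the opposite pattern, 3.11 ± 0.76 in Mandarin and 2.76 ± 0.65 in S03W4 against 11.98 ± 0.91, 12.85 ± 0.12 and 12.69 ± 0.15 in 2601R, Bayfield and PS46R. A further probe set, made for the same target sequence as the last, had 3.48 ± 0.25 in Mandarin and 3.04 ± 0.49 in S03W4 and at least 12.22 ± 0.77 elsewhere. It is therefore not a separate finding. The gene LOC100500577 had probe sets of opposite direction, of which 1 was at 12.03 ± 0.08 in Mandarin and at most 2.47 ± 0.12 elsewhere, whereas another was at 1.93 ± 0.17 in Mandarin and between 10.17 ± 0.41 and 10.92 ± 0.29 in Bayfield, PS46R and S03W4. In 2601R the latter was at 1.90 and 1.67 in replicates 3 and 5 and at 10.33, 10.82 and 10.56 in replicates 2, 4 and 6. Across all varieties, 14011 soybean probe sets (37.3%) were called in the moderated F-test, against 21 of the 23350 pathogen probe sets.

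**Figure D2:**
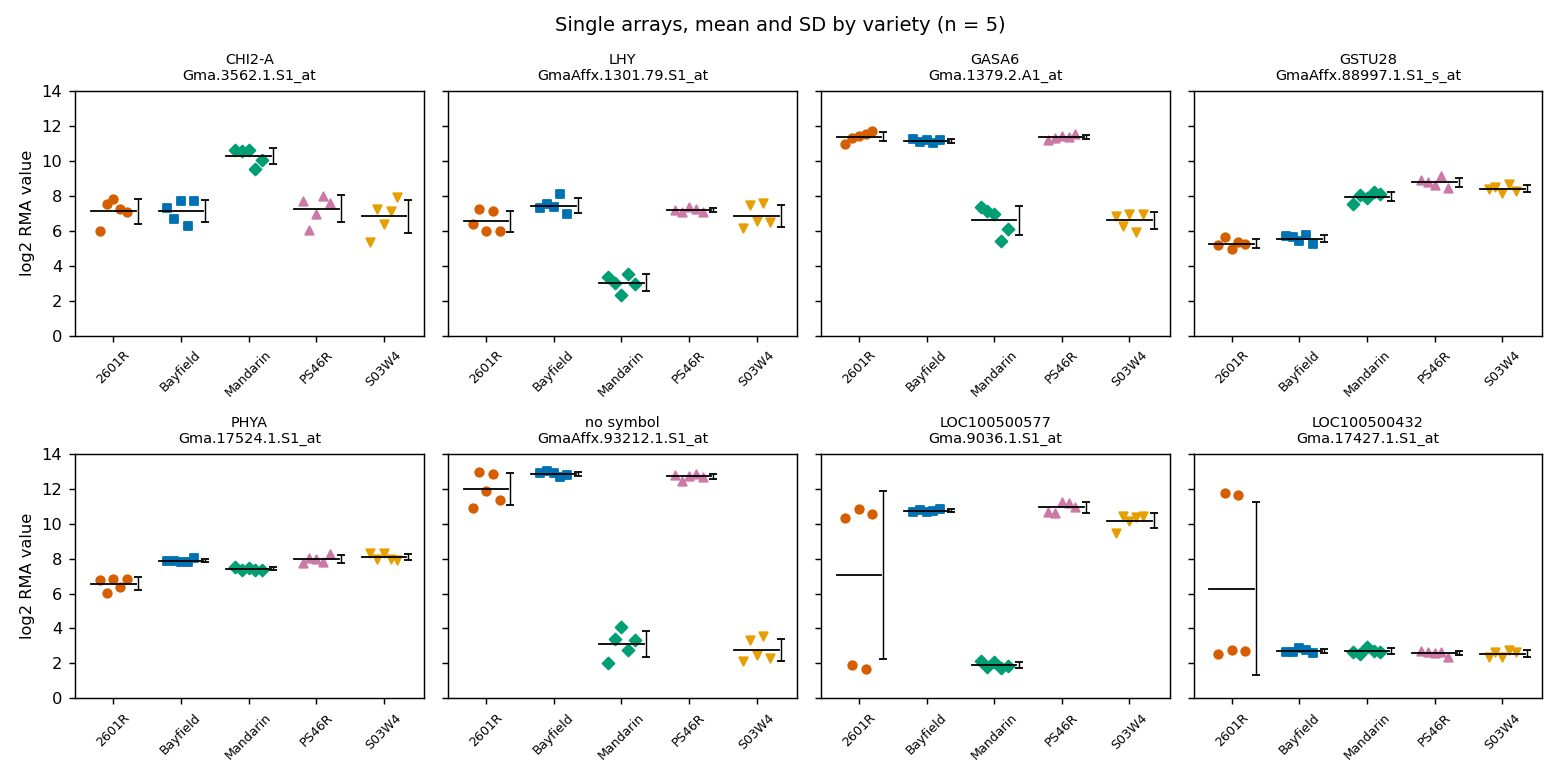
Log2 RMA values of 8 probe sets in the single arrays, grouped by variety, with the variety mean as a line and the SD as a bar (n = 5). LHY was lower and CHI2-A higher in all 5 Mandarin arrays than in any other array, GASA6 and a probe set without a gene were low in Mandarin and S03W4, GSTU28 was low in 2601R and Bayfield, and the arrays of 2601R split on LOC100500577 and LOC100500432.

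Mandarin was the variety with the most differences, and the 4 comparisons with it ask what its leaves express differently. LHY, a MYB factor of the circadian clock, was at 3.03 ± 0.47 in Mandarin and at 6.55 ± 0.61, 7.44 ± 0.43, 7.19 ± 0.13 and 6.87 ± 0.64 in 2601R, Bayfield, PS46R and S03W4, a difference of 3.52 ± 0.29 to 4.41 ± 0.29 (highest adjusted p = 2.7e-09). LUXC, another clock gene, was higher in Mandarin, 9.63 ± 0.32 against 7.05 ± 0.31 to 7.73 ± 0.30. The MYB factor MYB134 was at 1.98 ± 0.26, under the background, in Mandarin and at 5.66 ± 0.29 to 6.48 ± 0.49 elsewhere. MYB118 was also lower there (2.99 ± 0.26 against 5.33 ± 0.26 or more), while MYB177 (5.30 ± 0.44 against at most 3.08 ± 0.40) and MYB173 (5.83 ± 0.46 against at most 3.83 ± 0.77) were higher. Of the 25 probe sets of the list of clock, light and flowering genes, 15 were called in the F-test (16 adjusted over the list alone), 5 were lower in Mandarin than in each other variety and 2 were higher. As a list they were lower in Mandarin than in S03W4 (camera adjusted p = 0.000113), Bayfield (0.0176), 2601R (0.0418) and PS46R (0.0477). These calls were lost with an adjusted p = 0.40, 0.64, 0.70 and 0.70 with an estimated correlation. The call against 2601R was also not made with the 3′ index as a covariate (adjusted p = 0.0655) or without the 5 arrays of index above 2.5 (0.182), and with 1 value per gene neither this call nor that against PS46R was made. Of the 104 MYB probe sets, 47 were called (49 adjusted over the list alone), 13 were lower and 9 higher in Mandarin than in each other variety, and the list was called in no comparison with Mandarin.

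Genes of the chloroplast went both ways in Mandarin, and more of them were lower. CHLH, the H subunit of the magnesium chelatase of chlorophyll synthesis, was at 9.65 ± 0.16 in Mandarin and at 11.40 ± 0.09 to 11.63 ± 0.09 in the other varieties. CAB3, a chlorophyll-binding protein of the light-harvesting antenna, was at 11.34 ± 0.38 against 12.82 ± 0.22 to 13.08 ± 0.10. The Rubisco activase genes differed in direction: RCA14 (10.13 ± 0.20 against at least 10.94 ± 0.08) and RCAALPHA (10.12 ± 0.09 against at least 10.78 ± 0.12) were lower in Mandarin and RCABETA was higher (9.29 ± 0.24 against at most 8.28 ± 0.50). DXR2, an enzyme of the plastid pathway to isoprenoids, was at 7.87 ± 1.73 in Mandarin and at 10.90 ± 0.58 or more elsewhere. Of the 28 photosynthesis probe sets, 14 were called (14 adjusted over the list alone), with 10 lower and 1 higher in Mandarin than in each other variety. The list was lower in Mandarin than in 2601R, Bayfield, PS46R and S03W4 (camera adjusted p = 0.000172, 2.71e-05, 0.000113 and 0.000128), and each comparison had an adjusted p = 0.081 with an estimated correlation. Of the 9 carotenoid probe sets, 6 were called (8 adjusted over the list alone) and 4 were lower in Mandarin than in each other variety, among them ZEP, the zeaxanthin epoxidase (9.06 ± 0.26 against at least 10.38 ± 0.26), and BCH5, a carotene hydroxylase (6.16 ± 0.42 against at least 7.32 ± 0.17). CYP97C10 was higher there (9.23 ± 0.24 against at most 8.60 ± 0.11). This list was lower in Mandarin than in Bayfield (adjusted p = 0.0338) and PS46R (0.0452), with an adjusted p = 0.21 with an estimated correlation for both. Against PS46R the call was not made without the 5 arrays of index above 2.5 (adjusted p = 0.0526), and neither call was made with 1 value per gene or with dim probe sets left out. Of the 13 probe sets of chlorophyll and heme genes, 4 were called (4 adjusted over the list alone), and the list was called in none of the 10 pairs. Besides CHLH these were SGR2, HO1 and HEMG, which had their highest mean in Mandarin. SGR2 was at 6.77 ± 0.33 there against 6.12 ± 0.34 to 6.53 ± 0.27, HO1 at 8.33 ± 0.12 against 7.89 ± 0.04 to 8.08 ± 0.11, and HEMG at 5.94 ± 0.10 against 5.56 ± 0.21 to 5.88 ± 0.12. None of the 3 was called against all 4 other varieties.

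Several phenylpropanoid genes were higher in Mandarin. C4H, the cinnamate hydroxylase, was at 9.80 ± 0.22 in Mandarin against 7.74 ± 0.58 to 8.28 ± 0.61, and 4CL4, a coumarate-CoA ligase, at 8.91 ± 0.38 against 7.21 ± 0.32 to 7.50 ± 0.20. CHI2-A, a chalcone isomerase of flavonoid synthesis, was at 10.29 ± 0.47 against 6.82 ± 0.97 to 7.26 ± 0.77, a difference of 3.03 ± 0.43 or more (highest adjusted p = 1.1e-05). CHI1B1, another chalcone isomerase, was at 2.43 ± 0.42 in Mandarin with 1 probe set and at 3.96 ± 0.58 to 5.70 ± 0.45 elsewhere. Of the 20 phenylpropanoid probe sets, 19 were called (20 adjusted over the list alone), 7 were higher in Mandarin than in each other variety and 1 was lower. The list was higher in Mandarin than in 2601R, Bayfield, PS46R and S03W4 (camera adjusted p = 0.000113, 0.0175, 0.0196 and 0.005). It was not called with an estimated correlation (adjusted p = 0.21, 0.50, 0.51 and 0.41 with an estimated correlation), and the calls against Bayfield and PS46R were not made with 1 value per gene or with dim probe sets left out. Of the 70 flavonoid probe sets, 29 were called (29 adjusted over the list alone), 6 were higher and 4 lower in Mandarin than in each other variety, and the list was called in no pair.

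Some heat shock and ribosomal protein genes were lower in Mandarin. The heat shock factor HSF-08 was at 3.35 ± 0.67 in Mandarin and at 5.51 ± 0.31 to 6.18 ± 0.36 elsewhere, and the small heat shock protein gene HSP23.9 at 4.53 ± 0.42 against 6.83 ± 0.19 to 7.29 ± 0.45. Of the 34 heat shock probe sets, 21 were called (22 adjusted over the list alone), 9 were lower and 1 was higher in Mandarin than in each other variety. Camera called the list lower in Mandarin than in 2601R, Bayfield, PS46R and S03W4 (adjusted p = 2.06e-05, 0.0044, 0.000295 and 0.000238), with an adjusted p = 0.21, 0.45, 0.29 and 0.28 with an estimated correlation. With 1 value for each of its 17 genes none of these 4 calls was made. Of the 11 ribosomal protein probe sets, 6 were called (8 adjusted over the list alone), 3 were lower in Mandarin than in each other variety, and RPS6 was at 4.03 ± 0.26 against 4.87 ± 0.30 to 5.32 ± 0.52. The ribosomal list was lower in Mandarin than in 2601R, Bayfield and PS46R (adjusted p = 0.000987, 0.0046 and 0.00299; adjusted p = 0.50, 0.59 and 0.58 with an estimated correlation). Its 11 probe sets are of 5 genes, and with 1 value per gene these 3 calls were not made. It was also lower in S03W4 than in 2601R (adjusted p = 0.000624, and adjusted p = 0.49 with an estimated correlation), a call not made without the 5 arrays of index above 2.5 (adjusted p = 0.112). DREB2A2, a drought-responsive factor, was at 3.05 ± 0.26 in Mandarin against 5.05 ± 0.28 to 5.64 ± 0.45. Of the 18 probe sets of the drought, cold and osmotic stress list, 12 were called (12 adjusted over the list alone), 3 were higher and 2 lower in Mandarin than in each other variety, and the list was lower in 2601R than in S03W4 alone (adjusted p = 0.0484, and adjusted p = 0.64 with an estimated correlation). That call was not made with the index as a covariate (0.0674), without the 5 arrays (0.34), with 1 value per gene or with dim probe sets left out.

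Defence, detoxification and transport genes went both ways in Mandarin. CYP74A1, an allene oxide synthase of jasmonate synthesis, was at 6.61 ± 0.28 in Mandarin against 4.18 ± 0.27 to 4.64 ± 0.32, AOC3, an allene oxide cyclase, at 7.69 ± 0.09 against 6.13 ± 0.20 to 6.83 ± 0.44, and the lipoxygenase LOX9 at 6.93 ± 0.54 against 4.50 ± 0.53 to 5.35 ± 0.15. The Kunitz trypsin inhibitor KTI-2 was lower, 8.06 ± 0.20 against 9.50 ± 0.43 to 10.39 ± 0.39. PGIP4, an inhibitor of fungal polygalacturonases, was at 5.30 ± 0.66 in Mandarin and 4.09 ± 0.49 in PS46R, and at most 2.09 ± 0.26, under the background, in the other 3 varieties. Of the lipoxygenase, redox and WRKY probe sets, 5, 10 and 9 were higher and 1, 7 and 3 lower in Mandarin than in each other variety. SIP1-4, an aquaporin, was at 6.43 ± 0.05 in Mandarin and 5.38 ± 0.97 in S03W4 against at most 2.98 ± 0.35 elsewhere. GASA6, a gibberellin-regulated peptide, was at 6.60 ± 0.82 in Mandarin and 6.59 ± 0.46 in S03W4 against 11.14 ± 0.09 to 11.39 ± 0.28. CYP28, whose symbol belongs to the cyclophilin series of soybean, was at 3.88 ± 0.28 in Mandarin and at 7.58 ± 1.81 to 8.18 ± 0.58 elsewhere. Of the 20 jasmonate probe sets, 6 were called (5 adjusted over the list alone) and 3 were higher in Mandarin, and the list was called in no pair. UDP-glycosyltransferases were lower in Mandarin than in Bayfield (adjusted p = 0.0044) and S03W4 (0.0104), with 6 of 12 probe sets called (7 adjusted over the list alone), UGT78K1 at 7.44 ± 0.51 against at least 8.75 ± 0.29, and adjusted p = 0.21 with an estimated correlation for both. Disease resistance genes were higher in Mandarin than in Bayfield (adjusted p = 0.0175, and adjusted p = 0.33 with an estimated correlation), with 17 of 30 probe sets called (18 adjusted over the list alone) and KNBS1 at 8.72 ± 0.44 against 5.97 ± 0.24 in Bayfield and 6.66 ± 0.62 to 7.93 ± 0.56 in the other 3 varieties. Protease inhibitors were lower in Mandarin than in Bayfield (adjusted p = 0.0269, and adjusted p = 0.21 with an estimated correlation), a call not made with 1 value per gene, with 3 of 11 probe sets called (3 adjusted over the list alone).

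In all, 4248 probe sets were specific to Mandarin, 2432 higher and 1816 lower than in each of the other 4 varieties. The pairs gave 9337 called probe sets against 2601R, 9530 against Bayfield, 8678 against PS46R and 10037 against S03W4, of which 2245, 2368, 2151 and 2648 differed by log2 1 or more. With the 3′ index as a covariate, chosen after seeing the data, 6980 probe sets were specific to Mandarin, and 4202 of the 4248 (98.9%) remained so. Without the 5 arrays of index above 2.5, also chosen after seeing the data, 79.6% of the 4248 remained so.

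**Figure D3:**
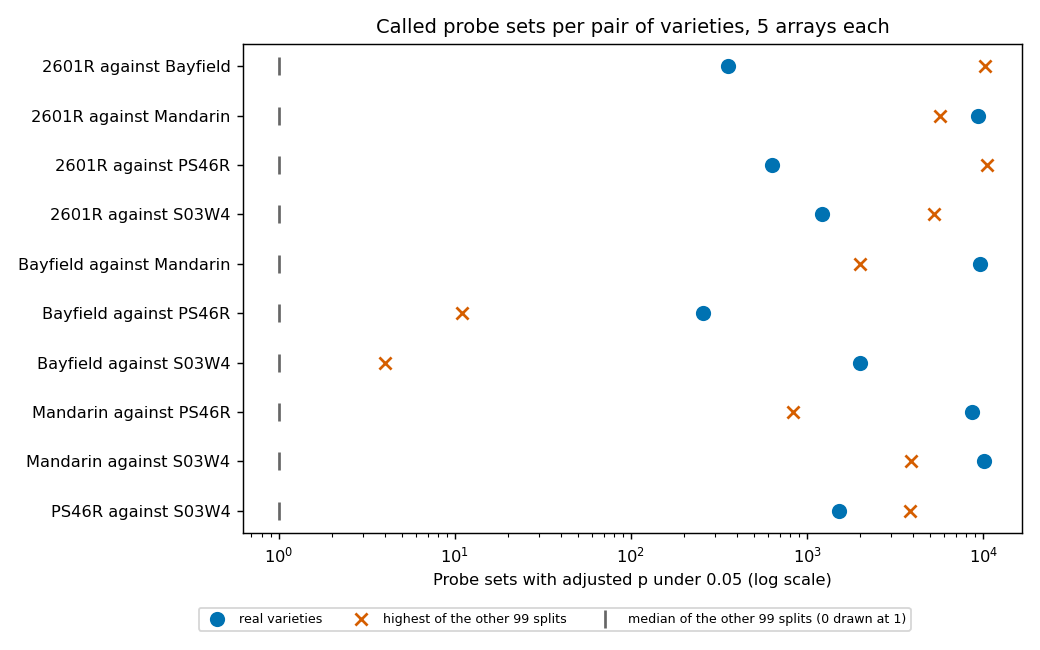
For each pair of varieties, the number of called probe sets (log scale) with the real varieties (filled points), and the highest and the median number in the other splits of the same 10 arrays into 5 and 5 (crosses and bars). In the pairs with Mandarin the real count was between 8678 and 10037, and in the pairs of 2601R with Bayfield, PS46R and S03W4 and in PS46R against S03W4 another split gave more.

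S03W4 was compared with each other variety to find what its leaves express differently. SEOM, a sieve element occlusion gene of the phloem, was at 2.12 ± 0.08, under the background, in S03W4 and at 4.61 ± 0.58 to 5.32 ± 0.29 elsewhere (highest adjusted p = 1.5e-06). CHS1, a chalcone synthase, was at 4.33 ± 1.08 in S03W4 and at 6.13 ± 0.67 to 7.03 ± 0.52 elsewhere. PDH (4.60 ± 0.89 against at least 6.01 ± 0.23) and the glutathione S-transferase GST3 (4.74 ± 0.25 against at least 5.76 ± 0.18) were also lower in S03W4. SIK2 (5.38 ± 0.67 against at most 3.95 ± 0.30), the cytochrome P450 CYP82A3 (5.03 ± 0.90 against at most 3.62 ± 0.68) and WRKY6 (5.31 ± 0.47 against at most 4.14 ± 0.86) were higher. CHI1B1 was higher with a probe set other than the one above, at 3.60 ± 0.70 in S03W4 and under the background in every other variety, so the size is not given. With the probe set above, CHI1B1 was at 5.70 ± 0.45 in S03W4, 5.49 ± 0.39 in 2601R and 4.98 ± 0.30 in Bayfield, so S03W4 did not stand apart. With its other probe set, CYP82A3 was at 6.92 ± 0.37 in S03W4 and 6.44 ± 0.28 in Mandarin against at most 3.84 ± 0.19. KR3, a disease resistance gene, was at 6.56 ± 0.39 in S03W4 and 6.38 ± 0.34 in Mandarin, against 3.69 ± 0.27 in Bayfield and 3.75 ± 0.17 in PS46R. In 2601R it was between these and widely spread (5.09 ± 1.48). Of the 104 WRKY probe sets, 51 were called (54 adjusted over the list alone). WRKY58 was at 8.57 ± 0.31 in S03W4, 8.25 ± 0.23 in 2601R, 8.11 ± 0.90 in PS46R, 7.20 ± 0.34 in Bayfield and 5.99 ± 0.13 in Mandarin. The WRKY list, factors tied to stress and defence, was higher in S03W4 than in Bayfield (adjusted p = 0.0123, and adjusted p = 0.49 with an estimated correlation) and than in 2601R (adjusted p = 0.00193, and adjusted p = 0.34 with an estimated correlation).

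The clock, light and flowering list was higher in S03W4 than in 2601R, Bayfield and PS46R (adjusted p = 0.000444, 0.0158 and 0.000624), with an adjusted p = 0.49, 0.64 and 0.50 with an estimated correlation. Against Bayfield this call was not made with the 3′ index as a covariate (adjusted p = 0.0655) or without the 5 arrays of index above 2.5 (0.132), nor with dim probe sets left out. Disease resistance genes were higher (adjusted p = 0.024, and adjusted p = 0.34 with an estimated correlation) and lipoxygenases lower (adjusted p = 0.0229, and adjusted p = 0.64 with an estimated correlation) in S03W4 than in Bayfield, the latter not with 1 value per gene. Cytochrome P450 (adjusted p = 0.0128), MYB (0.0349) and senescence genes (0.0464) were higher in S03W4 than in 2601R, with an adjusted p = 0.21, 0.45 and 0.215 with an estimated correlation. Without the 5 arrays of index above 2.5 these 3 lists and the WRKY list were not called in this pair (adjusted p = 0.0626, 0.432, 0.151 and 0.433), and the senescence list was not called with the index as a covariate (0.067). With 1 value per gene the cytochrome P450 and senescence lists were not called. There were 262 probe sets specific to S03W4 (183 higher, 79 lower) and 134 without those arrays. Leaving out 1 array gave 167 (without S03W4 replicate 3) to 495 (without S03W4 replicate 5). Bayfield against S03W4 had 2008 called probe sets, 931 with the index as a covariate and 707 without the 5 arrays. PS46R against S03W4 had 1524, with 1014 and 703 under the same alternatives. Without S03W4 replicate 3 these 2 pairs had 907 and 771, and without S03W4 replicate 5 they had 4351 and 2988, the extremes of leaving out 1 array.

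Bayfield and PS46R had 256 called probe sets, of which 129 differed by log2 1 or more, a root mean square difference of 0.23 between their means, and a Pearson correlation of 0.996 between their means across genes, which are not independent replicates. GSTU28, a tau class glutathione S-transferase, was at 5.56 ± 0.21 in Bayfield and 8.78 ± 0.25 in PS46R, a difference of -3.22 ± 0.15 (adjusted p = 2.6e-13). Its probe set is of the kind that matches several transcripts, and a sequence mismatch to the probes was not tested for this pair. PGIP4 was at 4.09 ± 0.49 in PS46R and under the background in Bayfield (2.04 ± 0.06, adjusted p = 6e-06). SSH2 (1.69 ± 0.31, adjusted p = 0.0051) and KTI-3, a Kunitz trypsin inhibitor (0.76 ± 0.15, adjusted p = 0.012), were higher in Bayfield. Lipoxygenases, enzymes that start the jasmonate pathway, were higher in Bayfield as a list (camera adjusted p = 8.78e-10, and adjusted p = 0.17 with an estimated correlation), as were the vegetative storage proteins of leaves (1.66e-07, and adjusted p = 0.21 with an estimated correlation). The 11 storage protein probe sets are of 2 genes, too few for a test with 1 value per gene. VSP27 was at 9.01 ± 1.09 in Bayfield and 6.26 ± 1.29 in PS46R, and VSPA at 11.93 ± 0.35 and 10.76 ± 0.39. The call of VSP27 in this pair was lost in 13 of the alternatives. LOX7 was at 9.14 ± 0.65 in Bayfield and 7.81 ± 0.75 in PS46R and LOX10 at 4.23 ± 0.83 and 3.47 ± 0.90, yet 0 of the 26 lipoxygenase probe sets and 2 of the 11 storage protein probe sets were called in this pair by themselves. Across all varieties 12 of the 26 (13 adjusted over the list alone) and 3 of the 11 (3 adjusted over the list alone) were called in the F-test. Protease inhibitors (adjusted p = 0.0041) and UDP-glycosyltransferases (0.013) were also higher in Bayfield, with an adjusted p = 0.081 and 0.21 with an estimated correlation, the latter not with 1 value per gene. The WRKY (adjusted p = 0.000113), pathogenesis-related (0.00133), disease resistance (0.013) and senescence (0.0269) lists were lower in Bayfield, with an adjusted p = 0.21, 0.21, 0.31 and 0.21 with an estimated correlation, and the senescence call was not made with 1 value per gene or with dim probe sets left out. Of the 17 pathogenesis-related probe sets 2 had a mean above background, so this call rests mostly on probe sets at background, as does that of the protease inhibitors (4 of 11). The pathogenesis-related list had 4 of 17 probe sets called (4 adjusted over the list alone) and the senescence list 6 of 12 (6 adjusted over the list alone). The disease resistance call was lost in at least 1 further alternative. With the index as a covariate the pair had 427 called probe sets and 2601R against Bayfield 104, so which pair has the fewest depends on this choice.

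2601R was set against Bayfield, PS46R and S03W4 in turn, over 5 arrays that split into 2 and 3 on LOC100500577 and LOC100500432. PHYA, the phytochrome A photoreceptor, was lower in 2601R (6.56 ± 0.36) than in every other variety (7.42 ± 0.07 to 8.08 ± 0.19), by 0.86 ± 0.13 or more (highest adjusted p = 4.1e-05), and was the one named gene among the 22 probe sets specific to 2601R. NES was at 7.47 ± 0.26 in 2601R and at 10.02 ± 0.14 in Bayfield and 10.02 ± 0.27 in PS46R, and GSTZ3, a zeta class glutathione S-transferase, at 6.84 ± 0.48 against 9.01 ± 0.19 and 8.89 ± 0.25. NES and GSTZ3 were at 5.88 ± 0.29 and 6.47 ± 0.30 in Mandarin and at 8.11 ± 0.22 and 6.96 ± 0.48 in S03W4. GSTU28 (5.27 ± 0.25) was lower in 2601R than in PS46R by 3.51 ± 0.15 (2601R minus PS46R -3.51, adjusted p = 4.4e-14), and GASA6 was higher than in S03W4 by 4.80 ± 0.27 (adjusted p = 9.7e-12). EN2 (2.23 ± 0.35, adjusted p = 0.00055) and AGL3L (1.72 ± 0.29, adjusted p = 0.0013) were higher in 2601R than in PS46R. CYP21, of the cyclophilin series, was higher in 2601R than in Bayfield by 1.06 ± 0.16 (adjusted p = 0.00089). BZIP111 was higher by 0.51 ± 0.12 (adjusted p = 0.0495), and by 0.39, no longer called, with the index as a covariate. As lists, lipoxygenases were lower in 2601R than in Bayfield (adjusted p = 0.000231, and adjusted p = 0.41 with an estimated correlation; not called with 1 value per gene) and heat shock genes higher (adjusted p = 0.0418, and adjusted p = 0.64 with an estimated correlation). The heat shock call was not made without the 5 arrays of high index (adjusted p = 0.109), with 1 value per gene or with dim probe sets left out. Against PS46R, the redox and glutathione S-transferase (adjusted p = 0.0106), pathogenesis-related (0.0153), phenylpropanoid (0.0296) and WRKY (0.0302) lists were lower in 2601R, with an adjusted p = 0.21, 0.33, 0.58 and 0.59 with an estimated correlation. The phenylpropanoid call was not made with the index as a covariate or without the 5 arrays (adjusted p = 0.189 and 0.261), nor the WRKY call without the 5 arrays (0.277), and neither was made with 1 value per gene. With dim probe sets left out the WRKY call was not made. The pathogenesis-related call was lost in at least 1 further alternative. Of the 79 redox probe sets, 38 were called in the F-test (41 adjusted over the list alone).

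The counts for 2601R depended on which of its arrays were used and on the 3′ index, which was higher in 3 of its 5 arrays. These 3 are replicates 2, 4 and 6, so within 2601R the index cannot be told apart from their split from replicates 3 and 5. Without the 5 arrays of index above 2.5, 2601R keeps replicates 3 and 5 alone, and fewer arrays also lower its counts. Against Bayfield 354 probe sets were called, 104 with the index as a covariate and 71 without the 5 arrays of index above 2.5. Leaving out 1 array gave between 77 (without Bayfield replicate 2) and 8802 (without 2601R replicate 3). Against PS46R 632 were called, with 413 and 228 under the same alternatives and 347 (without 2601R replicate 6) to 5314 (without 2601R replicate 3) without 1 array. Against S03W4 1215 were called, with 2903 and 436 under the alternatives and 736 (without 2601R replicate 6) to 1631 (without S03W4 replicate 5) without 1 array. The probe sets specific to 2601R were 14 higher and 8 lower, those specific to PS46R 27 higher and 42 lower (69), and those specific to Bayfield 5 higher and 7 lower (12). Leaving out 1 array gave 11 to 187, 59 to 72 and 5 to 32. No probe set specific to PS46R or Bayfield has a gene symbol other than a locus number.

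The title of the series is about genetically modified soybeans, and its labels do not say which varieties are modified. From general knowledge, 2601R and PS46R carry glyphosate tolerance, so these 2 varieties were set against Bayfield, Mandarin and S03W4. The annotation used here names no probe set of EPSPS, the enzyme that glyphosate inhibits. It gives no gene for 28546 of the 37593 soybean probe sets, so the array may still hold one. The genes highest in 2601R and PS46R relative to the other 3 were GASA6 (3.27 ± 0.17), which was also at 11.14 ± 0.09 in Bayfield, FAD2-1A, an oleate desaturase (1.48 ± 0.19), and HSP23.9 (with another probe set than the one above, 0.98 ± 0.13). The SEs of this contrast take arrays as replicates and leave out the spread between the varieties of 1 side. In limma on the 5 variety means GASA6 had an unadjusted p = 0.0889. AKR1, the histone deacetylase HD2A, GST3, HSP90A1 and HSP90-1 were higher by 0.44 ± 0.13 to 0.84 ± 0.22. The calls on arrays of HSP90-1 and HSP90A1 were lost in 21 and 17 of the alternatives. GSTU47 and WRKY30 were also higher but under the background in all 3 of the other varieties, so the size is not given. CYP74A1 (-1.09 ± 0.12), LOX9 (-1.06 ± 0.18), the inositol phosphate synthase gene MIPS4 (-1.04 ± 0.21) and the amylase gene BMY2 (-0.98 ± 0.18) were lower. MIPS, the proline-rich wall protein gene PRP2, MYB121, SAN1A, DD2/63 and GASA14 were lower by -0.90 ± 0.18 to -0.57 ± 0.12. Without the 5 arrays of index above 2.5, the calls on arrays of AKR1 (adjusted p = 0.0812), GST3 (0.14), HSP90A1 (0.186), HSP90-1 (0.0621), MIPS4 (0.0598) and MYB121 (0.15) were not made. All 20 genes were chosen because both variety means lay on one side of the other 3, and Mandarin held the extreme mean of the 3 for most of them. With the variety as the replicate (limma on the 5 variety means), each had an adjusted p of 1 and 0 probe sets were called, with 303 at an unadjusted p under 0.05. With arrays as replicates 2582 probe sets were called, 1362 higher and 1220 lower, and with variety as a random effect 5. Both 303 and 2582 were the lowest of the 10 ways to set 2 varieties against 3, for which the counts ran to 6079 and 10288. This order depends on the fit. With the 3′ index as a covariate the counts for 2601R and PS46R were 778 and 5013, where the lowest were 387 and 2068, and without the 5 arrays of index above 2.5 they were 612 and 1978, where the lowest were 426 and 1198. In simulated data with the real differences between varieties kept, a planted difference of log2 1 was found on variety means in 0% of probe sets and one of log2 2 in 50%.

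**Figure D4:**
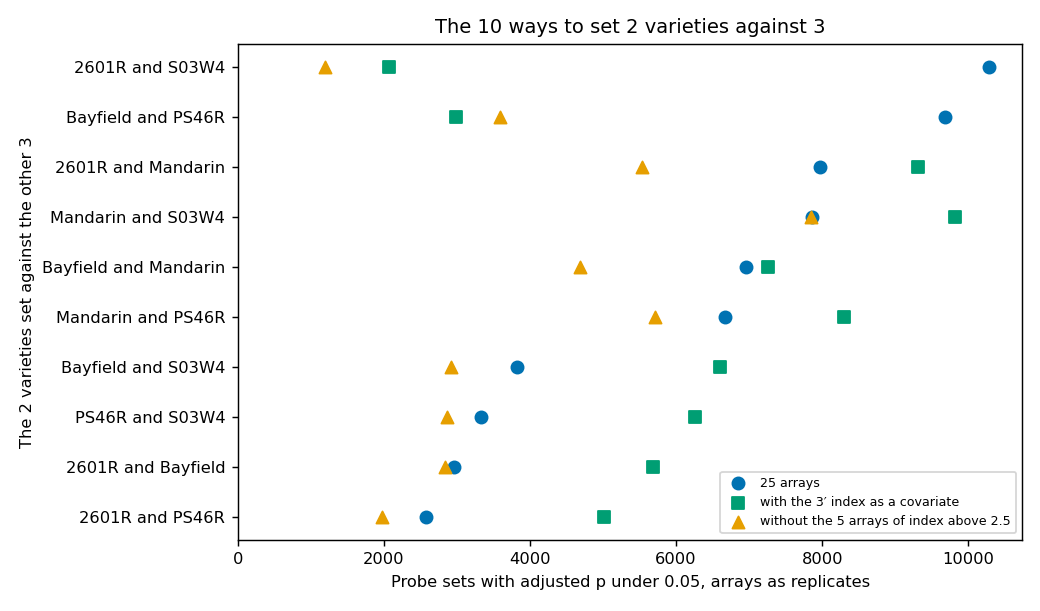
The number of called probe sets with arrays as replicates for each of the 10 ways to set 2 varieties against 3, for all 25 arrays (circles), with the 3′ index as a covariate (squares) and without the 5 arrays of index above 2.5 (triangles). With all 25 arrays and no covariate, 2601R and PS46R had the lowest count, 2582 (5013 with the index and 1978 without the 5 arrays). 2601R and S03W4 had the highest, 10288, which became 2068 with the index and 1198 without the 5 arrays.

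Lists of other tissues and of further gene families complete the account. Of the 55 probe sets of seed storage and maturation genes, 11 (20%) had a mean above background and 5 were called (2 adjusted over the list alone). In Mandarin 1 was higher and 2 were lower than in each other variety, and PM23 was at 7.27 ± 0.23 in Mandarin and 8.46 ± 0.20 to 9.04 ± 0.43 elsewhere. Of the 18 root nodule probe sets, 6 were above background and 1, N-36A, was called (1 adjusted over the list alone), at 4.45 ± 0.23 in Mandarin against at most 3.78 ± 0.19. Neither list was called in any pair. With the preset correlation of camera, the seed list was called lower in 2601R than in Bayfield without the 5 arrays of index above 2.5. The adjusted p was 0.00735, against 0.646 in the main fit and 0.0638 with the index as a covariate. It was called lower in S03W4 than in Bayfield with the index (0.0388, against 0.341 in the main fit and 0.0943 without the 5 arrays). Called in the F-test were 26 of 49 cytochrome P450 probe sets (27 adjusted over the list alone), 36 of 98 bZIP (36), 10 of 41 NAC (5), 19 of 33 aquaporin (20), 6 of 13 sugar transport (6), 5 of 13 glyoxalase (6), 13 of 30 iron and phosphate (15) and 9 of 20 cell division and wall growth (11), the numbers in parentheses adjusted over the list alone. In Mandarin both directions occurred in most of these families. Higher and lower there than in each other variety were 5 and 2 cytochrome P450, 5 and 2 bZIP, 3 and 0 NAC, 5 and 1 aquaporin, 2 and 3 sugar transport, 1 and 1 glyoxalase, 2 and 2 iron and phosphate, and 1 and 0 cell division and wall growth probe sets. BZIP94 was at 3.60 ± 0.23 in Bayfield, 3.94 ± 0.33 in PS46R and 3.12 ± 0.13 in S03W4 and under the background in 2601R (1.69 ± 0.10) and Mandarin (1.62 ± 0.14). NAC12 was at 6.63 ± 0.73 in Mandarin against 4.23 ± 0.37 to 5.32 ± 0.50, the sucrose transporter SUT1 at 6.85 ± 0.29 against 7.68 ± 0.20 to 8.20 ± 0.41, and the ferritin gene SFERH-3 at 8.58 ± 0.42 against 10.00 ± 0.33 to 10.59 ± 0.36. In the other direction, the sugar transporter SWEET42 was at 7.52 ± 0.22 in Mandarin against 6.50 ± 0.14 to 6.79 ± 0.15, and SFERH-4 at 7.53 ± 0.38 against 5.71 ± 0.89 to 6.46 ± 1.12. GLYI-23, a glyoxalase, was at 8.49 ± 0.24 in Mandarin and at 9.84 ± 0.21 to 10.31 ± 0.53 elsewhere, and GLYII-5 at 6.32 ± 0.08 against 5.81 ± 0.16 to 5.99 ± 0.13. Apart from the cytochrome P450 list, none of these families was called in any pair. In all, 51 of the 300 tests of 30 lists in 10 pairs were called with the preset correlation of 0.01 and 0 with an estimated correlation. Regroupings of the arrays gave a median of 22 list calls with the preset correlation. With 1 value per gene, 26 of 290 were called. The index as a covariate gave 59 calls, 46 of the 51 and 13 new ones. Leaving out the 5 arrays of index above 2.5 gave 49, 39 of the 51 and 10 new ones. New in both were 8, all with the preset correlation, since no estimated correlation was used in these alternatives. Without the 5 arrays, the calls that involve 2601R rest on its replicates 3 and 5 alone. In 2601R carotenoids (adjusted p = 0.114 in the main fit, 0.00442 with the index and 0.00369 without the 5 arrays) and clock, light and flowering genes (0.796, 0.00149 and 0.0222) were lower than in Bayfield. UDP-glycosyltransferases were higher in 2601R than in Mandarin (0.0962, 0.0347 and 0.00868). Compared with PS46R, in 2601R the vegetative storage proteins were higher (0.233, 0.00222 and 0.0104) and senescence genes lower (0.102, 0.00372 and 0.00986). In S03W4 protease inhibitors were lower than in Bayfield (0.13, 0.0388 and 0.0489). Vegetative storage proteins (0.0963, 0.00222 and 0.0131) and UDP-glycosyltransferases (0.285, 0.00506 and 0.032) were higher in S03W4 than in PS46R.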

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

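The tests of the 3′ index on the Mandarin differences and on 2601R with S03W4, of the Mandarin differences of log2 2 or more, and of the 3′ index and a mislabelled sample on 2601R replicates 3 and 5 were chosen after the result was seen.

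In each group of 5 arrays, the lowest or highest array was tested for its distance from the rest, and chance marks about 1 in 20 such groups. Of 30 groups of array measures 2 were marked (6.67%), and of 735 groups of named genes 36 (4.90%). Both array measures were those of Mandarin replicate 4, with a soybean median of 4.757 (next 4.844) and a Phytophthora median of 2.043 (next 1.96). The widest gaps among the named genes were CYP28 in S03W4 replicate 3 (4.35, next 8.3), XET1 in S03W4 replicate 1 (7.95, next 4.78) and PS46R replicate 2 (7.28, next 4.69), BZIP112 in 2601R replicate 2 (3.24, next 5.4), AKR1 in S03W4 replicate 5 (4.78, next 6.92) and PDH in S03W4 replicate 1 (3.04, next 4.77). Also far from the rest were MYB134 in 2601R replicate 2 (6.88), Mandarin replicate 6 (2.45) and S03W4 replicate 5 (5.64), HS1pro1 in Bayfield replicate 1 (3.21) and PS46R replicate 2 (5.06), and GmNAC109 in Bayfield replicate 2 (3) and S03W4 replicate 3 (4.87). In S03W4 these were KR3 (7.24), UGT78K1 (8.25), SGT3 (9.25) and LOC100500577 (9.46) in replicate 1, DREB2 (4.89) in replicate 3, and EXP4 (9.2) and MYB118 (4.93) in replicate 5. In PS46R they were KTI-3 (8.74), SWEET28 (6.62) and 1 of the probe sets without a gene (12.6) in replicate 2, EXP2 (6.93) in replicate 4, and the probe set of the widest range (3.45) in replicate 5. In Bayfield they were GmJAZ1 (7.3) and GOLS (3.55) in replicate 3, and C4H (7.64), HSP23.9 (7.17) and NIP1-8 (8.84) in replicate 4. In Mandarin they were SBP2 (2.93) and GLYII-6 (5.66) in replicate 1, VPE2 (9.89) in replicate 3 and PGIP (2.58) in replicate 4. In 2601R they were RCA14 (10.86) in replicate 4 and VPE (1.65) in replicate 5. Outside the soybean probe sets, 21 of 23350 pathogen probe sets (0.0899%) were called across varieties, and 7.53% had an unadjusted p under 0.05 in limma's F-test, against 49.9% of the soybean probe sets.

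Other groupings of the same arrays were compared with the real ones. Chance was excluded as the source of the whole count of 14011 probe sets across varieties (1 of 100 regroupings, highest other 1799). That some varieties differ follows from this, but not how many of the 14011 calls are due to chance. The real counts were also the highest for those specific to Mandarin (4248, highest other 0), S03W4 (262, 0), PS46R (69, 0), 2601R (22, 0) and Bayfield (12, 2). These regroupings mix varieties, so real differences widen the spread within groups and 4 calls of 1 sign are rare. They therefore cannot exclude chance for the specific probe sets of a single variety. Those of 2601R also need calls against Bayfield and S03W4, pairs for which chance was not excluded. In splits of the 10 arrays of a pair, chance was excluded for Mandarin against Bayfield (9530, 1985), PS46R (8678, 828), S03W4 (10037, 3894) and 2601R (9337, 5698). It was also excluded for Bayfield against PS46R (256, 11) and S03W4 (2008, 4). The share was under 0.05 for PS46R against S03W4 (1524, with 3 of 100 and highest other 3859) and 2601R against PS46R (632, with 4 of 100 and 10502). It was also under 0.05 for the gene lists (51, with 3 of 100 and 56). In each the highest other count was above the real one, and the shares were not adjusted over the tests, so chance was not excluded. The median of the other regroupings was 22 list calls, so many list calls with the preset correlation arise without the real grouping. Nor was it excluded for 2601R against Bayfield (354, with 6 of 100 and 10245) or S03W4 (1215, with 5 of 100 and 5283). The highest splits put 2601R replicates 2, 4 and 6 with Bayfield 1 and 5, or with PS46R 3 and 5. Their sides differed in mean 3′ index by 1.29 and 1.23, the largest of the splits drawn for each pair, so they point to that structure of the samples. The highest split of 2601R against S03W4 put 2601R 2 and 6 with S03W4 1, 2 and 3, all but S03W4 2 with an index above 2.5. Its sides differed by 0.92, against 0.13 for the real split and 1.06 for the largest drawn, so it too goes with the index. The highest split of PS46R against S03W4 differed by 0.74, against 0.71 for the real split and 0.90 for the largest drawn. The structure behind that split was not identified. The 10 ways to set 2 varieties against 3 are too few for a share under 0.05 (2582, highest other 10288).

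Mandarin stood apart from the other 4 varieties. The 3′ bias of the RNA as the whole cause was argued against by the 98.9% of its specific probe sets that stayed specific with the index as a covariate. A mismatch of Mandarin's own sequence to the probes as the whole cause was argued against by the 42.7% that were lower, since a mismatch lowers the signal. A mismatch that the other 4 varieties share would make Mandarin higher, and this share cannot exclude it. Probe sets responding singly were argued against by the 88.6% of 958 other probe sets of the same genes with the same sign (72.9% for any 2 probe sets of a gene). Among the 235 specific by log2 2 or more, 73.2% were lower, so for these a mismatch cannot be told apart from lower expression, as the bounds set for the test were 75% and 60%. A difference between the varieties stays open as untested, as does, for clock genes such as LHY, the time of day of harvest, which is not given in the sources used here.

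Differences that followed the 3′ index were the second pattern. Of the 10288 probe sets called for 2601R and S03W4 against the other 3 varieties, 16.8% stayed called with the index as a covariate, so 3′ bias is a candidate explanation for most of that split. For 2601R against Bayfield, 67 of 354 (18.9%) stayed called, with a median difference of 0.77 before and 0.50 after in the direction of the call and a median SE of 0.16 and 0.14. These calls ended because the difference became smaller, and since the index also differs between the varieties, bias and variety cannot be told apart for them. A difference between the varieties stays open as untested.

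Replicates 3 and 5 of 2601R differed from replicates 2, 4 and 6 by log2 3 or more in 22 probe sets. In 15 of them (68.2%) the S03W4 arrays of high index moved the same way by at least 0.333 of the gap, between the bounds of 75% and 25% set for the test. In 20 of the 22 they moved the same way by any amount. These 20 include small moves, in LOC100500432 (-0.32 against a difference of -9.02) and in a probe set without a gene (0.30 against 4.32). For the group as a whole, 3′ bias cannot be told apart from other causes. For LOC100500432 (11.75 and 11.63 against 2.52 to 2.76) and LOC100500577 (1.90 and 1.67 against 10.33 to 10.82) 3′ bias was argued against, since 0% of the low-index arrays of other varieties lay nearer to replicates 3 and 5. The probe set that moved by 0.30 had a mean of 3.53 in replicates 3 and 5 and 7.86 in replicates 2, 4 and 6. Bayfield and PS46R lay at 7.12 to 7.89 and Mandarin at 2.87 to 3.81. Another without a gene had 5.59 in replicates 3 and 5, 1.84 in the rest of 2601R and at most 1.92 in every other variety. The low-index arrays of Bayfield and PS46R, seen after the tests, argue against 3′ bias for these probe sets too. A mislabelled sample from another of the 5 varieties was argued against by distance, measured with both arrays left out of the means and of the choice of 500 probe sets: both lay at least 1.97 times as far from the mean of every other variety as the farthest array of that variety. They also lay 1.52 and 1.39 times as far from replicates 2, 4 and 6, which have a higher index, as the farthest of these 3, and replicate 3 was nearer to Bayfield (0.740) than to them (0.787), so the distances do not show that the 2 arrays are 2601R. The design names no groups within 2601R, so no biological explanation was tested; whether its 5 arrays came from seed of 1 kind was not tested either, and this bears on every mean and count of 2601R.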

How the results depend on the processing

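The index as a covariate, the analysis without the 5 arrays of index above 2.5 and the mean over all 6 control genes were chosen after seeing the data. The cause was not tested for any of the changes below, except that fewer arrays or fewer tests lower or raise counts by construction. No result reversed. The counts for Mandarin against each other variety stayed within 1.5 times under every alternative.

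Array weights gave 22417 probe sets across varieties (14011 without them), 13269 for 2601R against Bayfield, 10916 against PS46R and 6194 against S03W4, 929 for Bayfield against PS46R and 3198 against S03W4, and 2248 specific to 2601R, 109 to Bayfield and 135 to PS46R. The weights of 2601R replicates 3 and 5 were low (0.31 and 0.45). Leaving out either array also raised the count of 2601R against Bayfield (8802 and 4813), so the higher counts are not separate evidence. With the replicate block as a factor the counts were 7807 across varieties, 56, 288 and 602 for 2601R against Bayfield, PS46R and S03W4, 1013 for Bayfield and 807 for PS46R against S03W4, and 7, 3 and 163 specific to 2601R, Bayfield and S03W4; with the replicate block as a random effect, 145 for 2601R against Bayfield and 14 specific to 2601R. Replicate numbers did not pair the arrays. Adjustment over 10 contrasts gave 2633, 1878 and 2092 for 2601R against Bayfield, PS46R and S03W4, 633 and 3147 for Bayfield against PS46R and S03W4, and 2669 for PS46R against S03W4. A fit of the 2 varieties alone gave 55, 180, 326, 1327 and 532 for the same pairs without Bayfield against PS46R. Centring on pathogen probe sets gave 215 for 2601R against Bayfield.

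The index as a covariate gave 104, 413 and 2903 for 2601R against Bayfield, PS46R and S03W4, 427 and 931 for Bayfield against PS46R and S03W4, 1014 for PS46R against S03W4 and 6980 specific to Mandarin. Without the 5 arrays of index above 2.5 the counts were 71, 228 and 436 for 2601R, 707 and 703 for Bayfield and PS46R against S03W4, and 134 specific to S03W4. Those for 2601R then rest on its replicates 3 and 5 alone. For 2 varieties against 3, limma on variety means gave 0 (303 at an unadjusted p under 0.05), arrays as replicates 2582 (5013 with the index and 1978 without the 5 arrays) and variety as a random effect 5. Of 51 list calls, 0 were made with an estimated correlation and 26 with 1 value per gene.

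Leaving out 1 array gave 77 to 8802 for 2601R against Bayfield (354). It was 121, 8802, 88, 4813 and 92 without 2601R replicates 2 to 6, 204, 77, 109, 100 and 983 without Bayfield 1 to 5, 207, 184, 182, 190 and 172 without Mandarin 1, 3, 4, 6 and 7, 157 and 213 without PS46R 3 and 4, and 187 without S03W4 2. For 2601R against PS46R (632) it gave 347 to 5314: 393, 5314, 352, 1848 and 347 without 2601R 2 to 6, and 374, 364 and 1071 without PS46R 3, 4 and 5. For 2601R against S03W4 (1215) it gave 736 to 1631, with 773 and 736 without 2601R 4 and 6. Bayfield against PS46R (256) ranged from 189 to 333. For Bayfield against S03W4 (2008) it gave 907 to 4351: 3020 without 2601R 3, 955 and 1099 without Bayfield 2 and 3, and 1006, 907, 4191 and 4351 without S03W4 1, 3, 4 and 5. For PS46R against S03W4 (1524) it gave 771 to 2988: 793, 827 and 2563 without PS46R 1, 4 and 5, and 780, 771 and 2988 without S03W4 1, 3 and 5.

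Probe sets specific to 2601R (22) ranged from 11 to 187: 187, 11, 133 and 13 without 2601R 3, 4, 5 and 6, 12, 14 and 12 without Bayfield 2, 3 and 4, and 14 without PS46R 3. Those specific to Bayfield (12) ranged from 5 to 32: 32 and 26 without 2601R 3 and 5, and 5, 6 and 19 without Bayfield 2, 4 and 5. Those specific to PS46R (69) ranged from 59 to 72, and those specific to S03W4 (262) from 167 to 495, with 168, 167 and 495 without S03W4 1, 3 and 5.

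Of the values of named genes under the alternatives, 5895 kept their side of the threshold, 163 no longer passed it and 16 newly did. The call was never lost in 150 of 175 results, among them VSPA, SBP2, UGT1 and NAC19, which had none to lose in the pair tested and account for the 16. BZIP111 and LOX1.4 for 2601R against Bayfield were lost in 22 alternatives each, and GLYII-6 in that pair in 21. HSP90-1 and HSP90A1 for 2 varieties against 3 were lost in 21 and 17, and VSP27 for Bayfield against PS46R in 13. Of the list calls, 31 of 51 were made in every alternative that tested them, the estimated correlation and 1 value per gene aside. Among the rest were clock, light and flowering genes in Mandarin against PS46R and lipoxygenases in Bayfield against S03W4. Disease resistance genes in Bayfield against PS46R and pathogenesis-related genes in 2601R against PS46R were also among them. The index as a covariate added 13 list calls and leaving out the 5 arrays 10, of which 8 were in both; every other alternative added at most 5. The pathogenesis-related and protease inhibitor lists were not tested with dim probe sets left out, nor the storage proteins with 1 value per gene, since under 5 members remained. Signal over background limits the rest: 74.8% of soybean probe sets had a mean above 2.59, and the others had a mean over all arrays at or under it. Where no variety mean lies above it, a difference cannot be told from background.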

Other observations

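All tests here were planned except the neighbour tests by variety, which were not in the plan, and the counts of opposite probe sets and of gaps within varieties, which were chosen after the result was seen.

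A chromosome segment particular to 1 variety could hold neighbouring genes specific to that variety. Genes that several varieties share against several others are specific to none, so a count of specific genes cannot detect segments shared in that way. Among 6010 genes in gene order, 208 adjacent pairs were specific to the same variety. In 1000 shuffles the mean was 199 and the 95th percentile 218, so no excess was detected over all varieties. Mandarin held 1092 of the 1172 specific genes and dominates that count. Within 5 genes of each other, S03W4 had 7 pairs against a shuffled mean of 3.4 (permutation p = 0.054) and PS46R 1 against 0.038 (permutation p = 0.038), with an adjusted p = 0.324 for both over 12 tests. At 2 to 5 genes, without immediate neighbours, S03W4 had 5 pairs against 2.7 (permutation p = 0.15, adjusted p = 0.6) and PS46R had 0. Segments in these varieties stay open. In simulated data without planted segments 511 of 1000 shuffles gave as many pairs, and with planted segments 0. The planted segments were many runs of consecutive genes, counted within 5 genes of each other. Whether few or short segments would be found was not simulated.

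Of 149 genes with more than 1 Mandarin-specific probe set, 6 had probe sets of opposite sign, and in 3 of these both differed by log2 1 or more (LOC100500577, LOC100791698 and LOC547605). Every one of the 25 arrays lay nearest to the mean of its own variety over the 500 probe sets that part the varieties most, with that array left out of both. The exception is 2601R replicate 3, which lay nearer to Bayfield (0.740) than to its own variety (0.787) when replicate 5 was left out as well.

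A gap of log2 3 or more between the arrays of 1 variety was found in 25 probe sets of 2601R, 17 of S03W4, 13 of PS46R and 0 of Bayfield and Mandarin. In 2601R replicates 3 and 5 were apart in 22 of the 25, and replicates 2 and 6 were higher by 7.41 in 1 probe set without a gene. In S03W4 replicate 1 alone was apart in 14 of the 17, and was lower by 7.51 and 7.89 at 2 probe sets of LOC100790389, and replicates 2 and 4 were higher by 5.89 at a probe set without a gene. In PS46R replicate 1 was apart in 6 (4 of them of the ferritin gene SFERH-2), replicate 2 in 4 and both together in 3. No explanation was tested for the gaps in S03W4 and PS46R, which bear on the means of these varieties as those of 2601R do.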
